A study of Mus musculus with 12 samples.

How the data were processed

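RNA was measured in 10 libraries of mouse CD4+ T cells and Bach2 binding in 1 chromatin immunoprecipitation (ChIP) library with 1 input library. Per the labels' protocols, sorted naive cells were kept fresh or were stimulated for 3 days on plates coated with antibodies to CD3 and CD28 (10 μg/ml each). Th1 cultures received 20 ng/ml IL-12, Th2 cultures 20 ng/ml IL-4, Th17 cultures 20 ng/ml IL-6 with 2 ng/ml TGF-β1, and induced regulatory (iTreg) cultures 100 IU/ml IL-2 with 5 ng/ml TGF-β1. Neutralizing antibodies (10 μg/ml) against IFN-γ or IL-4, or both, were added in the helper conditions only. RNA libraries were made from 200 ng of total RNA with a TruSeq kit and sequenced on an Illumina HiSeq 2000, per the labels. The antibody in the ChIP was a rabbit anti-Bach2 made in house, and the input lysate had no antibody.

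The expression files hold FPKM values made by Cufflinks from 50-bp reads aligned to mm9 with TopHat, of which only unique ones were used, according to the labels' protocols. The deposited column is FPKM per the file headers, although the extension of the files names RPKM, and the planned tests had assumed RPKM. Both are normalized to transcript length and library size by the authors, so the tests were kept. Summed FPKM still differed by genotype, between 432450 and 437849 in WT and between 545183 and 553892 in Bach2KO iTreg libraries. It was 303348 in the naive library. The versions of TopHat and Cufflinks and the gene annotation are not given in the sources used here. Each file lists 23700 loci. For genes with a single start, the bounds of the deposited confidence interval lie 2 Poisson SD from the FPKM, which gives an estimate of the reads behind the value. Of the low genes checked, between 74.6 and 79.5% gave a whole number of reads within 0.02, so no count table was recovered and no count test was run. These implied reads cover counting error only.

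The peak list was made by MACS 1.4.0beta per the file headers, from 8992019 ChIP tags and 9999999 input tags with a p-value cutoff of 1e-05. Alignment was to mm9 with Bowtie per the submitters' processing notes. The deposited tag count of a peak is unnormalized per the file headers. The deposited score is 10 times the −log10 of the p-value of the peak, per the file headers. The fold enrichment, a ratio of ChIP tags to local background, and the FDR in percent were also made by the authors with MACS, per the file headers. The input library has no values of its own. Peak positions are 1-based mm9 positions as deposited.

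FPKM values were used with the authors' scaling. Bach2KO and WT iTreg libraries, 3 of each, were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 0.5), for genes with a mean of at least 0.5 FPKM over the 6 libraries. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The 4 single libraries stayed out of the fit because they carry no spread of their own. On this scale the change of a gene near 0 FPKM in either group is understated. Genes listed at 0 in every library of a group enter the fit and list medians at log2(0.5), and no fold is given for them. On simulated data over the same 11473 genes, the fit recovered 61.2% of 67 genes changed 1.5-fold, 77.6% of 67 changed 2-fold and 97% of 66 changed 4-fold, with 8 false calls. Far fewer genes were changed there than the 74.7% called in the data, so these rates do not carry over to the real calls. Strand and symbols came from the annotation of the same build: 21791 loci matched by symbol, 145 by synonym and 481 by overlap, while 1283 had no strand. The files repeat 472 symbols, and 72 loci had a failed estimate in an iTreg library.

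Gene lists, 23 in all, were fixed before the data were examined: helper and Treg programmes, naive and effector genes, receptors, transcription factors, metabolism, proliferation, and markers of other cell types, sex and RNA quality. The 21 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the lists. Listed genes under the filter of 0.5 FPKM were not tested. A gene near 0 FPKM in WT passed it only when high enough in Bach2KO. Counts and medians over tested members can therefore overstate a rise. Genes restricted to the naive, Th1, Th2 or Th17 library were those with at least 2 FPKM and a log2 value at least 1 above each of the other 3 libraries. The iTreg libraries had no part in choosing them. The filter on the iTreg libraries then left 474 of 492 naive-restricted, 115 of 166 Th1-restricted, 161 of 205 Th2-restricted and 296 of 368 Th17-restricted loci to test. Named genes follow a rule fixed beforehand: Bach2, the 10 largest rises and 10 largest falls among called genes whose replicates do not overlap and whose higher mean is at least 5 FPKM, up to 4 called members per list by smallest adjusted p, lineage genes fixed by name in any case, and 5 restricted genes per single library. Predicted, microRNA and snoRNA genes were skipped, and some genes under the rule are not reported here. Members that moved against their list and list members given as not called were named after their values were seen. This also holds for further Th17 programme members, genes in clusters and the 7 TGF-β response genes.

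Single libraries were compared with WT iTreg without a test. A gene counted as different when it differed at least 4-fold, in one direction, from each of the 3 WT libraries. List medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins. Peaks were assigned to a gene when the midpoint lay within 10 kb of its start. Shares of genes near a peak were compared by two-sided Fisher's exact test. For genes higher or lower in Bach2KO, a Mantel-Haenszel estimate over 10 expression strata was set beside it. Motif shares within 100 bp of the peak midpoint were compared with windows 2 kb to either side by McNemar's exact test. Peaks with the same score were ordered by fold enrichment. Proportions carry 95% Wilson intervals. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pyfaidx 0.9.0.4 and matplotlib 3.10.9.

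Alternatives covered the pseudocount, the filter, 2 rescalings, limma without trend or with robust variance, all 10 libraries in the fit, the replicate number as a block, each iTreg library left out, other margins, distances and peak sets. After the data were seen, fits without loci under 300 bp, without failed estimates, with equal sums over loci of at least 300 bp, without WT replicates 1 and 3, and with GC and length trends removed were added, as were motif windows around the summit and models of peak occurrence on the size of the change and restricted lists with each symbol once.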

Results

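CD4+ T cells of C57BL/6J mice, from spleen and lymph nodes, were profiled by RNA sequencing in 10 libraries and by ChIP sequencing of Bach2 in 1 library with 1 input. Bach2 is a transcriptional repressor of the CNC family that binds DNA together with small Maf proteins. Naive cells and cultures polarized to Th1, Th2 and Th17 gave 1 library each. Cultures in the iTreg condition, where TGF-β1 and IL-2 induce the Treg factor Foxp3, gave 3 wild type (WT) and 3 Bach2-deficient (Bach2KO) libraries. The ChIP library came from WT iTreg cells. The files give FPKM and no read totals. Reads implied over single-start genes came to between 18.2 M and 19.1 M in WT, between 20.1 M and 24.0 M in Bach2KO, 18.5 M in naive, 13.9 M in Th1, 14.0 M in Th2 and 12.4 M in Th17 cells. Between 10337 and 11497 loci reached 0.5 FPKM. The labels do not state whether replicates are separate animals or cultures, so the p-values of differences between genotypes measure only the spread between samples. P-values on peaks and motifs are computed over genes or peaks from the 1 ChIP library. Differences are on log2(FPKM + 0.5) and understate changes of genes near 0 FPKM.

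The deletion itself was read first. Bach2 (chromosome 4, 32504410 to 32673083, plus strand, mm9) stood at 17.6 ± 0.351 FPKM in WT and 3.81 ± 0.378 FPKM in Bach2KO iTreg cells (SD, n = 3 each), and it fell by 2.08 on the log2 scale (SE 0.074, limma with Benjamini-Hochberg, adjusted p = 4.4e-06). The remaining signal could not be assigned to an exon, since the values are per gene and the labels do not say which part was deleted. Among the single libraries Bach2 was at 23.4 FPKM in naive, 26.2 in Th1, 24.1 in Th2 and 64.6 in Th17 cells.

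How loss of Bach2 changes iTreg cells was asked by comparing Bach2KO with WT iTreg libraries. Bach2KO iTreg cells held less Foxp3 transcript and more of several Th1 and Th2 genes. Foxp3 fell from 72.5 ± 7.60 to 11.1 ± 7.56 FPKM, while Tbx21, which encodes the Th1 factor T-bet, rose from 0.107 ± 0.0575 to 11.7 ± 2.76 FPKM and the Th2 cytokine gene Il4 from 0.0270 ± 0.0468 to 11.5 ± 4.19 FPKM (SD, n = 3 each). Most listed genes of proliferation, glycolysis and cholesterol synthesis rose and most listed naive and memory T cell genes fell, although none of these lists passed in camera of limma with an estimated correlation (adjusted p = 0.247, 0.458, 0.341 and 0.247 in turn). Il17a, a cytokine gene of Th17 cells, was not called.

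Leaving aside microRNA, snoRNA and predicted genes, which the naming rule skips and some of which changed more, the 10 largest rises are given here. Plac8, a small cysteine-rich protein gene (chromosome 5, 100982752 to 101001224), went from 0.596 ± 0.45 to 191.6 ± 5.53 FPKM, a log2 rise of 7.55 (SE 0.308, limma adjusted p = 6.8e-06). Ly6a, which encodes the surface antigen Sca-1 (chromosome 15, 74825307 to 74828318), went from 15.9 ± 2.08 to 1559 ± 150.0 FPKM, a rise of 6.57 (SE 0.11, limma adjusted p = 6.8e-07). The cytokine gene Il9 reached 51.4 ± 27.5 FPKM, the granzyme gene Gzmb 30.6 ± 8.06 and the chemokine gene Ccl3 41.3 ± 21.9, each from under 0.5 FPKM in WT. Il9 was at 20.7 FPKM in Bach2KO replicate 2 and at 59.7 and 73.7 in the others. Scd1 and Fads2, fatty acid desaturase genes, rose by 5.25 and 5.28. Serpina3g (60.7 ± 7.07 FPKM), Ly6i (36.9 ± 2.04) and AA467197 (35.3 ± 2.45) completed the 10 largest rises. The value of Serpina3g is uncertain because its locus overlaps that of Serpina3f and its family holds near-identical copies, and the Ly6 genes are likewise a family of close relatives.

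Pyroxd2, an oxidoreductase gene (chromosome 19, 42800348 to 42827265), had the largest fall among the genes that met the naming rule, from 40.5 ± 4.94 to 0.313 ± 0.117 FPKM, and fell by 5.66 (SE 0.139, limma adjusted p = 1.6e-06). The peptide transporter gene Slc15a2 fell by 3.98, the alcohol dehydrogenase gene Adh1 by 3.79 (log2 −3.79) and the transcription factor gene Sox4 from 15.6 ± 1.29 to 0.744 ± 0.149 FPKM. Kcnip2, a potassium channel interacting protein gene, fell from 86.5 ± 1.29 to 6.93 ± 1.09 FPKM and Fam101b from 82.3 ± 13.5 to 7.91 ± 2.21 FPKM (SD, n = 3 each). Amigo2, Sec1, Cecr6 and Ntn5 stood between 6.75 and 14.8 FPKM in WT and under 1 FPKM in Bach2KO. Sec1 and Ntn5 lie beside each other on chromosome 7 and share 1 peak of Bach2 within 10 kb.

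**Figure D1:**
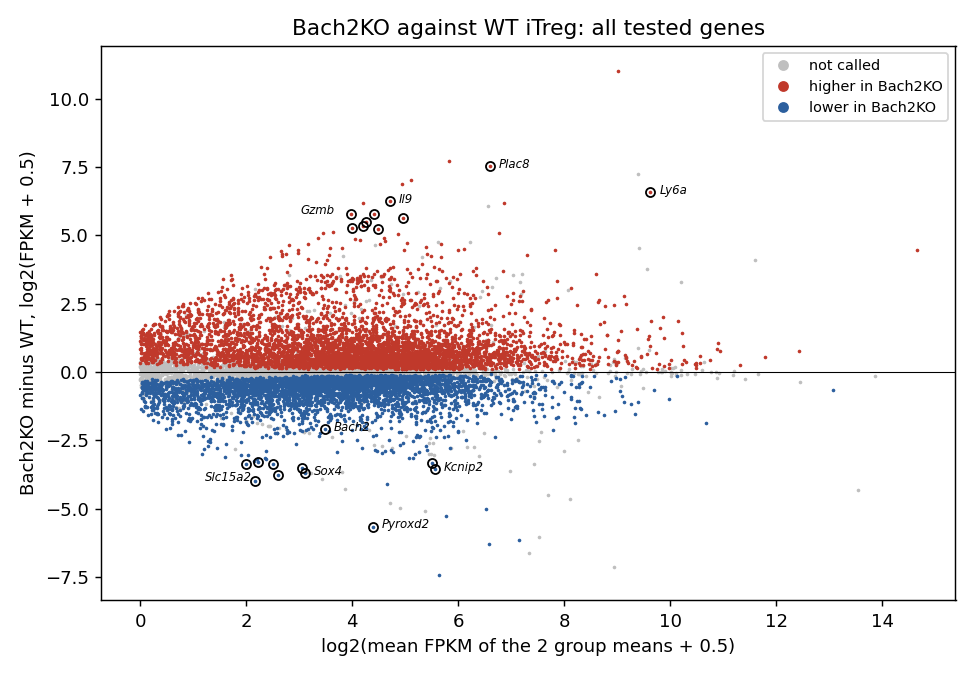
Log2 difference between Bach2KO and WT iTreg cells on log2(FPKM + 0.5) (y axis) against the log2 mean level (x axis) for the 11473 tested genes, with called genes in red (4709 higher) and blue (3857 lower). Circles mark Bach2 and the 20 genes with the largest rise or fall under the naming rule, from Plac8 at 7.55 to Pyroxd2 at −5.66.

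Of the T helper lists, the Th1 programme moved furthest. Of its 20 tested members 17 rose, 1 fell and 2 were not called, with a median of 2.90 (camera of limma, adjusted p = 3.8e-05; adjusted p = 0.247 with an estimated correlation). Ifng, the Th1 cytokine gene, rose by 4.31 but varied among Bach2KO libraries (10.6, 22.8 and 3.99 FPKM), while the factor genes Eomes and Runx3 rose by 4.69 and 3.09 and the chemokine receptor gene Cxcr3 by 4.47. The member that fell was Il18r1, an IL-18 receptor chain gene, at −0.62, and Stat4 (0.35) and Fasl (0.22) were not called. Of 15 tested Th2 programme members (23 listed) 11 rose and 1 fell, with a median of 1.75 (camera adjusted p = 0.0121; adjusted p = 0.458 with an estimated correlation). Gata3, the Th2 factor gene, rose from 9.16 ± 0.54 to 17.3 ± 2.73 FPKM (log2 0.87, limma adjusted p = 9.4e-04), the receptor gene Ccr4 from 11.2 ± 0.907 to 80.2 ± 8.69, and Asb2 from 0.224 ± 0.127 to 14.6 ± 4.89. Il13 was listed at 0 in the 3 WT libraries and at 15.6, 6.65 and 16.8 FPKM in the Bach2KO libraries. Maf, a factor gene of the list, fell by 1.65.

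The Th17 programme did not differ from other genes by camera, with 8 of 15 members higher, 2 lower and a median of 0.42 (camera adjusted p = 0.279; adjusted p = 0.471 with an estimated correlation), but passed by fry, which tests against no change (adjusted p = 0.0292). Il17a was at 0.992 ± 0.292 FPKM in WT and 1.11 ± 0.692 in Bach2KO (log2 0.04, limma adjusted p = 0.91), a difference whose sign turned in several alternatives. The members that rose included Irf4, Hif1a and Batf, which act in activated T cells of several lineages. Tmem176a (2.154), Tmem176b (1.693), Ahr (1.169), Stat3 (0.718) and Rora (0.418) rose as well. The IL-6 receptor gene Il6ra fell by 2.18, and Ccr6 (−1.955) fell too.

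**Figure D2:**
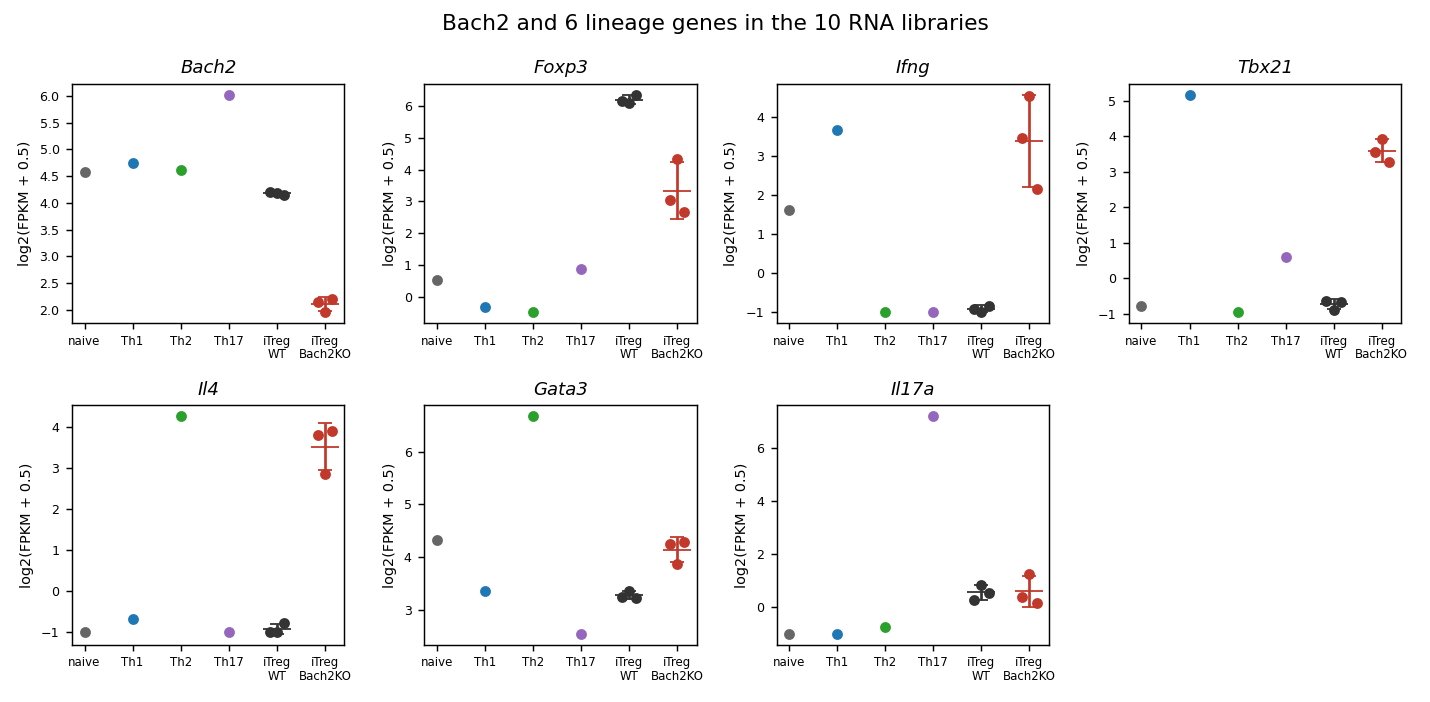
Bach2 and 6 lineage genes on log2(FPKM + 0.5) (y axis) in the naive, Th1, Th2, Th17, WT iTreg and Bach2KO iTreg libraries (x axis), a point per library, with the mean and SD of the 3 libraries for iTreg cells. Foxp3 is high in WT iTreg cells, Tbx21 and Il4 rise in Bach2KO, and Il17a stays level between the iTreg genotypes, with no call.

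The Treg programme was split. Foxp3 fell by 2.84 (SE 0.423, limma adjusted p = 0.0012), with 19.7 FPKM in Bach2KO replicate 2 against 7.68 and 5.81 in the others, and the ectonucleotidase gene Nt5e fell from 86.5 ± 3.33 to 35.2 ± 1.56 FPKM. Ikzf4, Itgae and Nrp1 were the other members that fell, at −1.47, −1.25 and −1.77. Of 27 tested members 19 rose, with a median of 1.19 (camera adjusted p = 0.0121; adjusted p = 0.458 with an estimated correlation). Those that rose included Il2rb, an IL-2 receptor chain gene (108.6 ± 5.01 to 365.8 ± 16.2 FPKM), and Tigit, an inhibitory receptor gene (0.638 ± 0.137 to 26.4 ± 6.52 FPKM). Naive and memory T cell genes fell in 20 of 24 members, with a median of −1.37 (camera adjusted p = 1.5e-05; adjusted p = 0.247 with an estimated correlation). The homing receptor gene Ccr7 fell from 453.8 ± 6.13 to 178.9 ± 6.05 FPKM, and Cd55 fell by 2.99. Ly6c1 (4.22) and Bcl2 (0.92) rose, and Il7r (0.35) and Satb1 (0.21) were not called.

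Effector and cytotoxic genes rose in 16 of 20 tested members (31 listed) and fell in 3, with a median of 1.90 (camera adjusted p = 0.00588; adjusted p = 0.247 with an estimated correlation). S100a6, a calcium-binding protein gene, went from 5.76 ± 1.37 to 210.9 ± 24.1 FPKM, Lgals1, a galectin gene, from 92.9 ± 9.29 to 514.8 ± 33.6, and the activation marker gene Cd44 from 15.7 ± 0.854 to 51.1 ± 1.48. The perforin gene Prf1 (−1.81), Klrd1 (−1.20) and Ctsw (−0.91) fell. Effector cytokine genes rose in 20 of 24 tested members (31 listed) and none fell, with a median of 2.31 (camera adjusted p = 6.7e-04; adjusted p = 0.458 with an estimated correlation). Lif went from 0.113 ± 0.0668 to 19.4 ± 10.0 FPKM and Ccl5 from 0.581 ± 0.103 to 6.05 ± 0.575, while Il17a (0.04), Il17f (0.04), Xcl1 (−0.73) and Ccl20 (−0.33) were not called. Chemokine receptors and integrins went both ways, 11 higher and 9 lower of 23, with a median of 0.32 (camera adjusted p = 0.991; adjusted p = 0.991 with an estimated correlation) that was −0.003 under quantile normalization. Inhibitory and costimulatory receptors rose in 10 of 20 members and fell in 4 (median 0.46, camera adjusted p = 0.225; adjusted p = 0.458 with an estimated correlation), with Havcr2, which encodes TIM-3, at 0.0124 ± 0.0125 in WT and 4.87 ± 0.186 FPKM in Bach2KO.

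The most uniform rises were in proliferation and metabolism. All 28 proliferation genes rose, with a median of 3.36 (camera adjusted p = 1.4e-12; adjusted p = 0.247 with an estimated correlation). Ccna2, the cyclin A2 gene, went from 6.85 ± 0.102 to 96.2 ± 0.892 FPKM and Top2a, the topoisomerase of dividing cells, to 212.4 ± 6.29 FPKM, a rise of 3.69. Glycolysis and hypoxia genes rose in 24 of 26 members, with a median of 2.58 (camera adjusted p = 1.1e-06; adjusted p = 0.458 with an estimated correlation). The glycolytic enzyme genes Eno1 and Pgam1 reached 225.9 ± 6.67 and 251.0 ± 24.1 FPKM from 35.7 ± 4.35 and 35.9 ± 4.40. Slc2a3 (0.49) and Pdk1 (−0.43) were not called. Cholesterol synthesis genes rose in all 22 tested members, with a median of 1.98 (camera adjusted p = 2.1e-08; adjusted p = 0.341 with an estimated correlation). Fdps, the farnesyl diphosphate synthase gene, went from 10.3 ± 0.708 to 114.1 ± 6.78 FPKM and Lss from 4.01 ± 0.226 to 28.1 ± 0.956.

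T cell receptor response genes rose in 18 of 21 members (median 1.15, camera adjusted p = 0.00372; adjusted p = 0.458 with an estimated correlation), with the survival gene Bcl2l1 at 60.9 ± 9.84 FPKM from 10.5 ± 1.94, and the feedback inhibitor gene Spry1 fell. Interferon response genes rose in 12 of 19 members and fell in 2, with a median of 1.44 (camera adjusted p = 0.0121; adjusted p = 0.471 with an estimated correlation). Bst2, which encodes tetherin, went from 10.5 ± 1.77 to 60.5 ± 8.58 FPKM, while Usp18 (−0.64) and Ifit2 (−0.45) fell. AP-1, CNC and small Maf factor genes, whose products bind the same DNA sites as Bach2, rose in 10 of 16 members and fell in 4 (median 1.09, camera adjusted p = 0.101; adjusted p = 0.458 with an estimated correlation). Junb rose from 33.1 ± 3.23 to 163.7 ± 7.52 FPKM and Atf3 from 0.0761 ± 0.0705 to 5.49 ± 0.664, and Maf, Mafk, Nfe2l2 and the paralog gene Bach1 (−0.65) fell. Oxidative stress and haem genes rose in 12 of 19 members and fell in 5 (median 0.98, camera adjusted p = 0.11; adjusted p = 0.458 with an estimated correlation), with the thioredoxin gene Txn1 at 203.7 ± 16.4 FPKM from 45.4 ± 3.92.

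**Figure D3:**
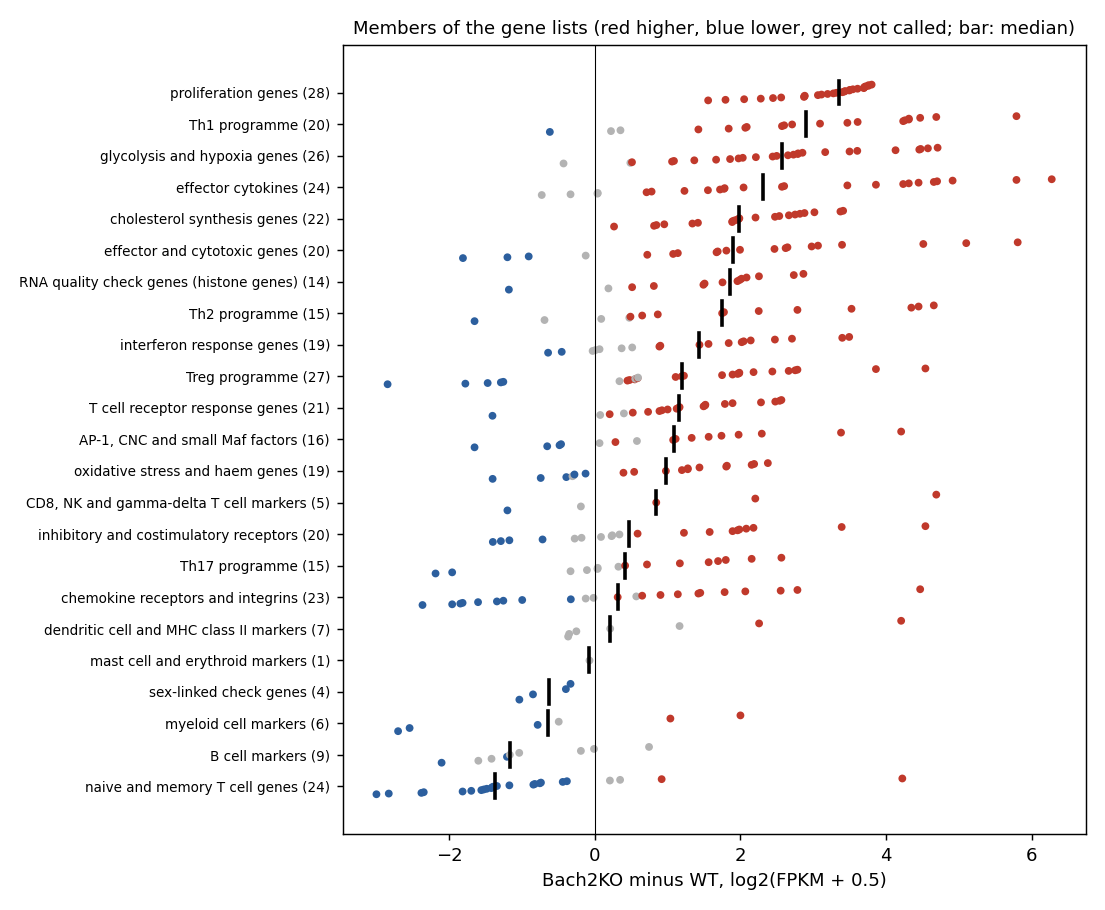
Log2 difference between Bach2KO and WT iTreg cells (x axis) of each tested member of the 23 gene lists (y axis, tested members in brackets), red for higher, blue for lower and grey for not called, with a bar at the median. All 28 proliferation genes lie to the right of 0 and 20 of 24 naive and memory T cell genes fell.

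Markers of other cell types were uneven between the WT libraries. The B cell marker gene Ly6d was at 16.8, 1.79 and 9.37 FPKM in WT replicates 1, 2 and 3, and the MHC class II gene H2-Aa at 49.7, 5.67 and 22.5. Of 9 B cell markers 0 rose and 2 fell (median −1.16, camera adjusted p = 0.279; adjusted p = 0.754 with an estimated correlation). The calls were for Ly6d (−2.10, limma adjusted p = 0.0393) and Cd79a (−1.20, limma adjusted p = 0.0438), and both were lost without a filter (adjusted p = 0.0657 and 0.0723), with robust variance, and on leaving out any 1 iTreg library other than WT replicate 2. The call of Ly6d was also lost with the replicate number as a block (limma adjusted p = 0.0659). Without WT replicate 2 the list passed in camera of limma at an adjusted p of 0.00985, and against WT replicate 2 alone, a choice made after the data were seen, its median turned to 0.218 over 7 tested members with 1 higher and 0 lower. Of 7 dendritic cell and MHC class II markers 2 rose (median 0.21, −0.050 with equal sums over loci of at least 300 bp and −0.043 with GC and length trends removed; camera adjusted p = 0.492; adjusted p = 0.781 with an estimated correlation), the factor genes Batf3 and Zbtb46. Against WT replicate 2 alone that median was 1.979 with 6 of 7 higher (camera of limma, adjusted p = 0.0144). Of 6 myeloid markers 2 rose and 3 fell (median −0.64, camera adjusted p = 0.279; adjusted p = 0.458 with an estimated correlation), with the integrin gene Itgam at 3.70 ± 0.602 FPKM in WT and 0.143 ± 0.0398 in Bach2KO. Of 5 CD8, NK and gamma-delta T cell markers 3 rose and 1 fell (median 0.85, camera adjusted p = 0.279; adjusted p = 0.46 with an estimated correlation), with Cd8a at 2.23 ± 0.124 FPKM in Bach2KO. The single tested mast cell and erythroid marker, Gata1, was not called (−0.08). All 4 tested Y-linked genes fell, from Eif2s3y at −1.03 to Uty at −0.33, and were also lower in each of the rescalings, which all moved Bach2KO down. Histone genes, listed as mostly without poly(A) tails to check RNA selection, rose in 12 of 14 members and fell in 1 (median 1.86, camera adjusted p = 0.00588; adjusted p = 0.458 with an estimated correlation). This rise cannot separate a difference in RNA selection from a change in expression of these genes.

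Across the genome 8566 of 11473 tested genes were called by limma with Benjamini-Hochberg adjustment (74.7%), 4709 higher and 3857 lower in Bach2KO, of which 1681 and 856 changed at least 2-fold. The values of the 2 genotypes did not overlap in 9106 genes, 79.4% against 10% by chance. In every list the same number of members passed when adjusted over the list alone, except for B cell markers, where it was 0. The split of calls rests on the scaling: it was 3715 higher and 4890 lower under quantile normalization and 3326 higher and 5439 lower with equal sums over loci of at least 300 bp, with the median of all genes at 0.071, −0.094 and −0.181 in turn. The 12 list calls, 11 up and 1 down, were all lost with an estimated correlation, while fry gave 19.

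Whether Bach2KO iTreg cells take on genes of other lineages was asked with genes restricted to 1 single library. By camera of limma the lists of the Th1 and Th2 libraries were shifted up in Bach2KO iTreg cells and those of the naive and Th17 libraries down, with members going both ways in each, and none of the 4 passed with an estimated correlation. Of 115 tested Th1-restricted genes (166 listed) 71 rose and 12 fell, with a median of 1.33 (camera adjusted p = 1.1e-05; adjusted p = 0.105 with an estimated correlation). Il12rb2, the IL-12 receptor chain gene, went from 0.127 ± 0.0199 to 11.7 ± 2.78 FPKM and Nkg7, of cytotoxic granules, from 6.23 ± 1.51 to 22.9 ± 4.24. Of 161 tested Th2-restricted genes (205 listed) 101 rose and 14 fell, with a median of 1.23 (camera adjusted p = 2.1e-06; adjusted p = 0.0842 with an estimated correlation). Akr1c18, a steroid dehydrogenase gene at 162.0 FPKM in the Th2 library, went from 2.39 ± 0.651 to 7.95 ± 2.94. Of 474 naive-restricted loci 73 rose and 299 fell (median −0.57, camera adjusted p = 5.8e-11; adjusted p = 0.0549 with an estimated correlation). Of 296 Th17-restricted loci 83 rose and 128 fell (median −0.25, camera adjusted p = 0.00245; adjusted p = 0.0549 with an estimated correlation). Repeated symbols count once per locus, and Rn4.5s enters the naive list 10 times. With each symbol once, chosen after the data were seen, the naive list had 465 members and a median of −0.60 and the Th17 list 295 and −0.25 (camera of limma, adjusted p = 6.2e-11 and 0.00214; adjusted p = 0.0499 for both with an estimated correlation). Il17f, at 668.3 FPKM in the Th17 library, was at 9.73 ± 1.44 in WT and 11.2 ± 6.40 in Bach2KO iTreg cells, while Gpr15, a gut homing receptor gene, rose from 0.640 ± 0.214 to 2.72 ± 1.11.

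When list genes also had to stand above WT replicate 1, with the fit on WT replicates 2 and 3, the naive list had a median of 0.072 (adjusted p = 0.573) and the Th17 list 0.154 (68 higher and 44 lower, adjusted p = 0.887), with the Th1 and Th2 lists at 1.33 and 1.52. This choice removes genes high enough in WT iTreg cells to fall, so a higher median follows from it by construction. Membership rests on single libraries. Across the 11473 genes, which are not independent replicates, the change in Bach2KO was correlated with the difference of each helper library from the naive one. Pearson r was 0.475 for the Th1 library (Spearman 0.495), 0.458 for Th2 (0.503) and 0.334 for Th17 (0.396). Each difference subtracts the same naive library, so changes common to the helper libraries enter every r. These values therefore do not separate likeness to a lineage from such common changes.

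**Figure D4:**
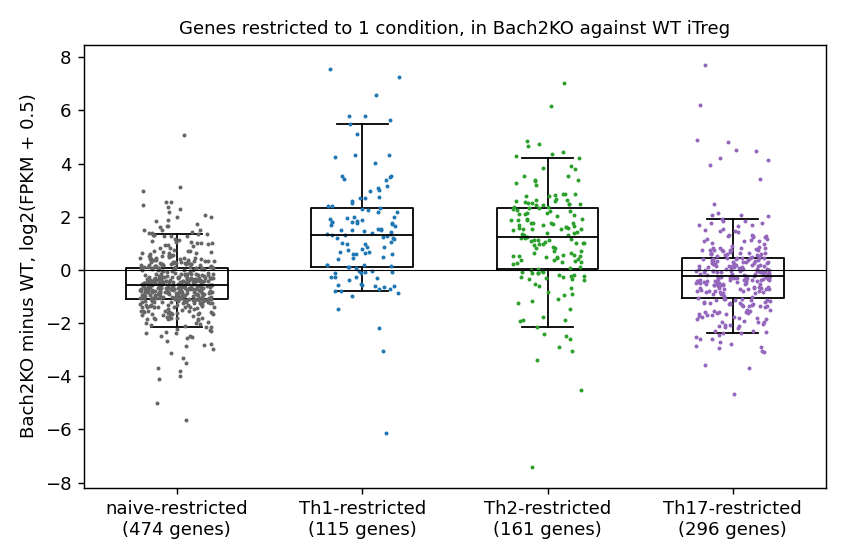
Log2 difference between Bach2KO and WT iTreg cells (y axis) of tested genes restricted to the naive, Th1, Th2 or Th17 library (x axis), a point per gene, with the median, the quartiles and whiskers at the 5th and 95th percentiles. The medians are −0.57, 1.33, 1.23 and −0.25.

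The single libraries were set beside WT iTreg cells to place the iTreg state among the other conditions. The Th1 and Th2 libraries carried the factor of their own lineage and the Th17 library its cytokine, and Foxp3 was low in all 4, at 0.952 FPKM in naive, 0.308 in Th1, 0.226 in Th2 and 1.35 in Th17 cells against 72.5 ± 7.60 in WT iTreg cells (SD, n = 3). Tbx21 was at 35.5 FPKM in the Th1 library, Gata3 at 101.9 in Th2, and Il17a at 144.9 in Th17. None of these differences has a replicate check.

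Among the genes restricted to the naive library, Hspa1b and Hspa1a, inducible HSP70 genes, were at 233.5 and 175.8 FPKM against 0.123 ± 0.0859 and 0.132 ± 0.0959 in WT iTreg cells, and the inflammasome-related genes Pydc3 and Pydc4 at 69.6 and 21.0. Rnu11, a short RNA gene, was at 98.0 FPKM and varied from 0 to 40.1 among WT iTreg libraries. Interferon response genes had a median of 1.44 above WT iTreg cells and AP-1, CNC and small Maf factor genes 1.43, and T cell receptor response genes 1.01, each at percentile 100.0 of 10000 random lists. Naive and memory T cell genes had a median of 0.04 (percentile 99.6), and the proliferation genes −1.74 (percentile 0.0). The library had 106 genes higher and 437 lower by at least 4-fold than each WT library, or 149 and 353 with median ratio scaling and 169 and 305 with quantile normalization.

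In the Th1 library 758 genes were higher and 347 lower than in each WT iTreg library, in the Th2 library 793 and 465, and in the Th17 library 457 and 194. A WT library set against the other two gave between 22 and 26 higher and between 13 and 20 lower. The genes most restricted to the Th1 library were Nkg7, Tbkbp1, Tbx21, the chemokine gene Ccl5 at 25.5 FPKM and Il12rb2 at 151.2. Those of the Th2 library were March10 at 32.6 FPKM, Akr1c18, Fam198a, Il4 at 18.6 and Adamtsl3. Those of the Th17 library included Il17f, Il17a, Gpr15 at 57.7 FPKM and the IL-1 receptor gene Il1r1 at 38.8. Proliferation genes had medians of 2.57, 2.96 and 2.41 above WT iTreg cells in the Th1, Th2 and Th17 libraries, and glycolysis and hypoxia genes 3.61, 3.70 and 2.46, all at percentile 100.0. The 4 single libraries held Xist at between 48.7 and 156.2 FPKM and Y-linked genes at under 0.05, while the iTreg libraries held Xist at under 0.01 and Eif2s3y at between 29.1 and 68.9, so condition and sex of the mice are confounded in these comparisons.

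Where Bach2 binds in iTreg cells was asked with the ChIP library, which has no replicate. The list holds 22494 peaks with a median length of 591 bp, a median of 29 tags and a median fold enrichment of 12.8, and 11.5% of ChIP tags lay in peaks. Peak midpoints lay within 1 kb of a start in 9.1% (95% Wilson interval 8.8 to 9.5%), from 1 to 10 kb in 21.4%, from 10 to 100 kb in 54.8% and further in 14.7%. By annotation 6.8% were exonic, 51.0% intronic and 42.2% intergenic. The highest written score (3233) was at a peak from 10012559 to 10014226 on chromosome 19, with 456 tags, intergenic and nearest to Incenp. Peaks in an intron of Map2k3 (chromosome 11, 60748607 to 60749767, score 3220) and in an intron of Gm14005 (chromosome 2, 128253607 to 128255867, score 3136) followed. A score of exactly 3100, taken as a cap, was shared by 24 peaks. Among these the fold enrichment was largest at intergenic peaks near Pabpc2 (chromosome 18, 40037139 to 40037941) and near Nek6 (chromosome 2, 38327086 to 38328988). The score does not rank the capped peaks against each other or against the higher scores. The reference annotation has a Bach2 gene model that begins upstream of the Bach2 locus in the expression files. That model held 43 peaks, of which 11 lay in the locus of the expression files and 32 upstream of it, among them the strongest (chromosome 4, 32336329 to 32338646, 618 tags, score 3100). Only the locus of Gm20388, with 87, held more.

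Peaks near named genes are given next. The peak at the start of the peroxiredoxin gene Prdx1 (chromosome 4, 116357283 to 116358961) had 357 tags and a fold enrichment of 42.6, that at Txn1 351 tags and 39.1, and that at the cystine transporter gene Slc7a11 145 tags and 84.8. Il9 had a peak downstream (chromosome 13, 56577883 to 56578795, 199 tags, fold enrichment 52.8), Tigit a peak at its start (148 tags, 60.5), Ccl3 a peak with 135 tags and 119.6, and Ly6a and Ly6i shared a peak between them (110 tags, 53.9). The 3 peaks near the start of Foxp3 had 36, 26 and 24 tags with fold enrichments of 6.69, 6.63 and 7.89, and Gata3 had 2 peaks near its start, of 88 and 51 tags.

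Whether genes near peaks respond to the loss of Bach2 was asked next. Of genes higher in Bach2KO 2033 of 4654 (43.7%) had a peak within 10 kb of the start, against 1107 of 2833 (39.1%) of genes not called, an odds ratio of 1.21 (Fisher's exact test, two-sided, adjusted p = 1.8e-04) that was 1.11 over expression strata (adjusted p = 0.0599). Of genes lower in Bach2KO 1579 of 3795 (41.6%) had a peak, an odds ratio of 1.11 (adjusted p = 0.0382), 1.07 over strata (adjusted p = 0.183). The difference between higher and lower genes did not pass (Fisher's exact test, odds ratio 1.09, p = 0.0573). Genes that rose at least 4-fold had a peak in 49.9% of cases and genes that fell at least 4-fold in 47.4%. In a logistic model with 10 expression strata, chosen after the data were seen, the odds ratio was 1.142 per log2 unit of rise (95% interval 1.084 to 1.202) and 1.125 per unit of fall (1.04 to 1.217). For genes lower in Bach2KO the call was lost within 2 kb (odds ratio 1.08, adjusted p = 0.231) and with a mean of at least 2 FPKM (1.10, adjusted p = 0.0856), and the ratio was 0.99 within 50 kb.

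**Figure D5:**
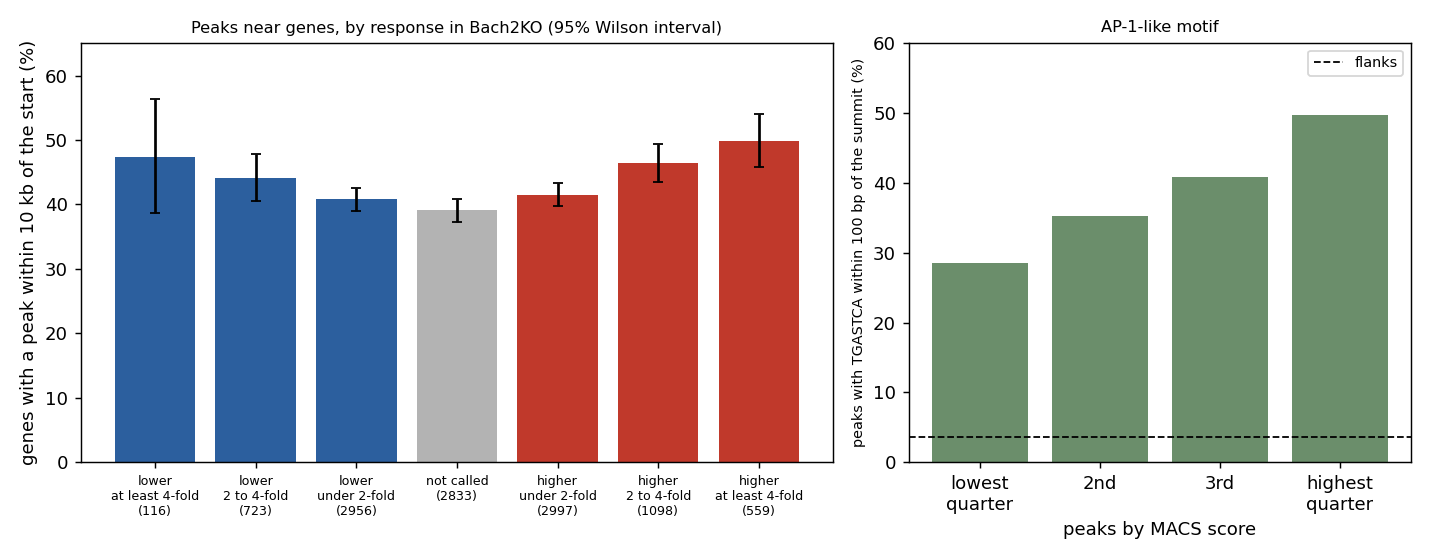
Left, percent of genes with a Bach2 peak within 10 kb of the start (y axis) by response in Bach2KO (x axis, genes in brackets), with 95% Wilson intervals; the share is 39.1% in genes not called and 49.9% in genes that rose at least 4-fold. Right, percent of peaks with TGASTCA within 100 bp of the summit (y axis) by rank of MACS score (x axis), from 28.5 to 49.8%, with the share in flanks as a dashed line.

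Naive-restricted and Th17-restricted genes had a peak within 10 kb more often than other expressed genes, 221 of 471 (46.9%, adjusted p = 0.0434) and 170 of 357 (47.6%, adjusted p = 0.0434) against 3916 of 9440 (41.5%) by Fisher's exact test. Th1-restricted genes (74 of 162, 45.7%, adjusted p = 0.395) and Th2-restricted genes (84 of 201, 41.8%, adjusted p = 0.942) did not pass. These comparisons of restricted genes were not stratified by expression. None of the 4 lists passed within 2 kb (adjusted p = 0.848) or within 50 kb (adjusted p = 0.769), and the naive list did not pass with the better-scoring peaks (adjusted p = 0.131). The motif TGASTCA, the site of AP-1 and of Bach factors, lay within 100 bp of the midpoint of 31.3% of peaks against 3.7% of flanks 2 kb away, and the longer TGCTGASTCA in 7.5% against 0.2% (McNemar's exact test, p at or under 1e-300, the smallest value written). Around the summit, chosen after the data were seen, TGASTCA was in 38.6% of peaks. It was in 22.6% of peaks within 1 kb of a start and in 40.2% of those further away. In the narrower window within 50 bp of the summit, TGACTCA was the most enriched of all 7-base words read on either strand, in 30.2% of peaks and 1.74% of flanks. Within 10 Mb of Bach2 on chromosome 4, 39 of 56 tested genes were called (69.6% against 74.7% elsewhere, Fisher's exact test, odds ratio 0.78, p = 0.441).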

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

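The number of called genes was 8566, 9528 without a filter, 7590 with a mean of at least 2 and 4806 (2861 higher, 1945 lower) with a fold of at least 1.5, by construction. Leave-one-out fits gave between 7746 and 8644 calls, and the fit without WT replicates 1 and 3 gave 6375, where the lone WT library is assumed to vary like the others. Treating the replicate number as a block gave 7886. Of 98 named genes 93 kept direction and side of the threshold throughout. Among the gene list tests 442 values were the same, 15 stronger, 12 weaker and 11 reversed, and among the named genes 2024 the same, 19 weaker and 7 reversed. A count test was not run, since whole reads were not recovered for all genes. Depth limits the genes near 0 FPKM. Fits without loci under 300 bp, with equal sums, without WT replicates 1 and 3 and with GC and length trends removed, and restricted lists with each symbol once, were chosen after seeing the data. Except where the construction shows it, the cause was not tested.

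With an estimated correlation adjusted p was 0.247 for the Th1 programme, naive and memory, effector and cytotoxic, and proliferation genes, 0.458 for the Th2 and Treg programmes, effector cytokines, T cell receptor response, glycolysis and histone genes, 0.471 for interferon response and 0.341 for cholesterol genes. For restricted genes it was 0.0549 (naive), 0.105 (Th1), 0.0842 (Th2) and 0.0549 (Th17). Lists also above WT replicate 1 gave 0.573 for naive and 0.887, reversed, for Th17, where genes high in WT are removed by construction. By fry the Th17 programme (0.0292), chemokine receptors (0.005), inhibitory receptors (5.2e-05), AP-1 (2.6e-05), oxidative stress (3.2e-05), myeloid (3.2e-05) and CD8 and NK lists (2.4e-05) passed.

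The test of chemokine receptors and integrins reversed with a pseudocount of 0.1 (0.996), a mean of at least 2 (0.767), all 10 libraries (0.998), the replicate block (0.977), without loci under 300 bp (0.977) and without WT replicates 1 and 3 (0.912), and spanned 0.87 to 0.99 in leave-one-out fits. AP-1 factors passed without a filter (0.0345), with quantile normalization (0.0362), with equal sums (0.0249) and with GC and length trends removed (0.0425). Oxidative stress genes passed without a filter (0.0316) and with equal sums (0.0248). B cell markers spanned 0.00985 to 0.539 in leave-one-out fits and reversed without WT replicates 1 and 3 (0.912). The dendritic cell and MHC class II list spanned 0.232 to 0.957, reversed without WT replicate 2, and passed without WT replicates 1 and 3 (0.0144).

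The difference of Il17a (log2) was −0.008 with median ratio scaling, −0.168 with quantile normalization, −0.139 with equal sums, −0.247 without WT replicates 1 and 3 and −0.351 with GC and length trends removed, and spanned −0.288 to 0.270 in leave-one-out fits.

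The odds ratio of a peak near lower genes was 1.08 within 2 kb, 0.99 within 50 kb and 1.1 with a mean of at least 2. For restricted genes within 2 kb it was 0.94 (naive), 0.94 (Th1), 0.85 (Th2) and 0.91 (Th17), and within 50 kb 1.18 (naive), 0.94 (Th1) and 1.06 (Th17). With the better-scoring peaks it was 1.21 for naive. Within 5 Mb of Bach2 the odds ratio was 1.02.

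Counts against WT iTreg cells (higher, lower) move with the margin by construction. With a log2 difference of at least 1 they were 366 and 1603 (naive), 2034 and 1339 (Th1), 1962 and 1611 (Th2), 1379 and 928 (Th17), and with at least 3 they were 37 and 219, 285 and 131, 346 and 167, and 149 and 75. With a pseudocount of 0.1 the lower counts were 781 (naive) and 537 (Th1), and Th17 had 719 and 345. With quantile normalization naive had 169 higher.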

Other observations

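The tests in this part were chosen after the results were seen, except for median ratio scaling and quantile normalization. Genes of the TGF-β response, listed after their values were seen, mostly fell in Bach2KO iTreg cells. Smad7, a feedback inhibitor of TGF-β signalling, fell from 66.7 ± 3.12 to 15.1 ± 1.19 FPKM (SD, n = 3 each), and Skil (−1.03), Ski (−0.80), Tgif1 (−1.22), Smad6 and Itgae (−1.25) fell too, while Pmepa1 rose by 0.21. Smad7 was at 74.7 FPKM in the naive, 27.9 in the Th17, 3.48 in the Th1 and 3.73 in the Th2 library.

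Genes changed at least 4-fold lie together on chromosomes more often than in shuffles. Windows of 1 Mb with 4 or more such genes numbered 16, against a mean of 9.68 in 10000 shuffles of the changed genes over all tested positions, of which 203 gave as many (permutation p = 0.0204). Some windows hold tandem families: Ly6a, Ly6i and Ly6c1 rose while Ly6d in the same window fell, and Scd1 and Scd2 (14.8 to 298.9 FPKM) rose while Sec31b beside them fell by 2.21. The fall of Ly6d rests on WT replicates 1 and 3 (16.8 and 9.37 FPKM, against 1.79 in replicate 2), and its call was lost in several alternatives. Serpina3f, Serpina3g, Serpina3h and Serpina3i rose as well. Il4 and Il13 rose beside Irf1, and Sec1, Ntn5, Car11 (−3.05) and Dbp (−2.92) fell in a window where Dkkl1 rose by 2.68. Reads shared between family members were not separated. These genes were chosen after their values were seen.

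The upward shift of the Th1- and Th2-restricted lists, whose calls did not pass with an estimated correlation (adjusted p = 0.105 and 0.0842 in camera of limma), could come from scaling, from GC content and gene length, or from a weaker response to TGF-β. Their difference from the Th17-restricted list was not tested. The lowest median of the Th1 and Th2 lists was 1.081 over 3 rescalings and 1.122 with GC and length trends removed, which argues against those causes. The 7 TGF-β response genes had a median of −1.224, but they were listed after their values were seen, so this is no test of a weaker response. A weaker response and an effect of Bach2 on these genes could both lower them, and no iTreg culture without TGF-β was measured, so this stays open.

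The fall of naive and memory T cell genes could reflect RNA from B cells in WT replicates 1 and 3, or scaling. The list differed by a median of −0.009 between WT replicates 1 and 2, and −0.014 between WT replicates 3 and 2, so B cell RNA did not raise it. Its highest median over 3 rescalings was −1.440, with median ratio scaling, where the median of all genes was 0.003. All 3 rescalings moved Bach2KO down against WT, so they could only lower this list. They cannot test whether scaling added to its fall, though the list stayed under the median of all genes.

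The larger share of genes near a peak among genes that changed more could follow expression or gene density. The odds ratio per log2 of rise was 1.142 with 10 expression strata (95% interval 1.084 to 1.202). For this trend, that argues against expression as the whole cause. Over called genes, strata lowered the odds ratio from 1.21 to 1.11 for higher genes (Mantel-Haenszel test, adjusted p = 0.0599). For lower genes it went from 1.11 to 1.07 (Mantel-Haenszel test, adjusted p = 0.183). Neither passed over strata, so part of the excess went with expression. With the density of starts within 100 kb added, the odds ratio per log2 of rise was still 1.142 (95% interval 1.084 to 1.202). A covariate that left the estimate unmoved is no test of gene density, so that explanation stays open. Peaks near genes do not show that Bach2 acts on them. Of the 10 splits of the 6 iTreg libraries into 3 and 3, the real one gave 8566 calls and the highest other 3, so 1 of 10 gave as many, which is too few splits (10) for a share under 0.05.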
